A study of Bifidobacterium longum subsp. infantis with 9 samples.

How the data were processed

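RNA from 9 cultures of Bifidobacterium longum subsp. infantis, 3 untreated, 3 given GMP and 3 given GMPP at 2 mg/ml, was hybridised to one-colour (Cy3) Agilent arrays, 1 culture per array. Per the labels' protocols, an on-column DNase step was part of the RNA extraction, RNA integrity was measured, and Agilent one-colour spike-ins were added before labelling; integrity values were not used here. Per the file headers, the arrays were read with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. The deposited scanner tables give for each spot a processed signal intensity, which per the file headers is background-subtracted and detrended within the array and not scaled between arrays, and the mean signal intensity with the median background intensity. The deposited series matrix holds 1 intensity per spot, on a linear scale and not centred. Its columns rank the spots as the processed signal does (rank correlation 1) and have medians of 674 to 675, and the sorted columns lie within a median of 0.458% of the mean of the 9 sorted signal columns, as quantile normalization would give. The submitters' processing notes name limma without a version or a role, and other steps of the authors are not given in the sources used here.

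Each array holds 15736 spots, 536 of them controls, and 9600 probes, of which 560 are printed 11 times and 9040 once. Every coding sequence has 4 probes; 169 carry a symbol and 2231 a locus tag alone. In the reference table of another assembly (ASM26996v1), matches were found for 142 of the symbols and 0 of the locus tags, so the names in the array files were kept and no coordinates are given. Spots marked as outliers by the scanner software were left out and spots of one probe averaged. The log2 processed signal was scaled by each array's 75th percentile over non-control probes. Probes entered if well above background on all 3 arrays of at least 1 group (44 did not), and 11 probes whose only spot was an outlier on some array were left out. The remaining 9545 probes were averaged per gene, which gave 2396 genes; 17 of these share a probe sequence with another gene, all had in each group a probe above background on at least 1 array, 2359 kept a probe when all 9 arrays were required, and 0 spots were saturated. For the named genes, 4 of 4 probes had the sign of the gene's change except in 5 comparisons of a gene with a small change, where 3 of 4 did. For arrays, their number limits the precision: the median SE of a fitted log2 change was 0.199.

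Genes were tested with limma 3.58.1 in R 4.3.3 (files read with the package data.table, version 1.17.8) in 1 fit of all 9 arrays with group as the only term (6 residual degrees of freedom), lmFit and eBayes, and Benjamini-Hochberg adjustment within each of the 3 comparisons at a threshold of 0.05. Lists were tested two-sided with limma's camera at a preset correlation of 0.01 against all other genes, with adjustment over the 25 lists, and again with a correlation estimated from the data. The 25 lists were chosen before the data were examined, as were the tests, the named-gene rule and the alternatives, except those said to have been added later. They covered the human milk oligosaccharide cluster H1, sialic acid use, hexosamine and lacto-N-biose use, glycoside hydrolases, sugar transport, the bifid shunt with lower glycolysis, urease, amino acid synthesis, peptide and amino acid transport, peptidases, ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase, chaperones, redox defence, fatty acid and phospholipid synthesis, cell wall and division, purine and pyrimidine synthesis, surface polysaccharide synthesis, pili and adhesion, DNA repair, mobile elements, transcriptional regulators, metal ion transport, and folate and B vitamin synthesis. Members were found by locus tag range or by words in the product name, and 30 memberships in 11 lists came from a stray word. As a check made after the intensity trend was seen, each list's mean change was set among 10000 random lists of genes from the same of 20 intensity bins. List means are given minus the mean of all genes, and gene changes minus the median gene, because the scaling moved the median of all genes by over 0.1.

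Named genes were, by rule, the 5 with the smallest p where no gene was called, the 3 members with the smallest p of each list past its threshold, and 12 genes fixed beforehand. These fixed genes were glycan genes set by locus tag and the phosphoketolase of the bifid shunt, found by its product. The alternatives were scaling by the median, by quantiles or by the 7 spike-in probes detected on all arrays; normexp background correction with an offset of 50; the series matrix values; no filter on dim probes or a filter on all 9 arrays; leaving out saturated probes; the brightest probe of each gene or single probes; a trended robust prior; array quality weights; only the 6 arrays compared; the slide or the replicate number as a block; stricter thresholds of 0.01 or of a 2-fold change; and leaving out each array. Leaving out untreated replicate 3 and GMPP replicate 2 together, and the lists without stray members, were added after seeing the data. Not every alternative can change a call. Leaving out saturated probes changed nothing, as 0 spots were saturated, and the slide block equals leaving out GMPP replicate 3. Leaving out an array of the third group keeps a comparison's changes and alters only their spread. The replicate block likewise keeps the changes and their correlation. Scaling by the median or by spike-ins shifts all genes of an array alike, so it cannot alter changes relative to other genes. Counts of alternatives are therefore not counts of separate checks. No samples were left out of the main comparisons. For the correlation of both effects, 1000 simulated sets of groups without effect that share the untreated arrays were drawn.

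The procedure was tested on simulated data for 2396 genes, with 200 of them changed, in 50 sets per comparison. For GMP minus untreated with independent noise, 29.8% of 1.5-fold, 63.3% of 2-fold and 87.1% of 4-fold changes were called, with 5.03% false calls; for GMPP minus untreated these were 30.7%, 63.9%, 86.9% and 4.5%, and for GMP minus GMPP 31.6%, 63.3%, 88.6% and 5.4%. With noise shared between genes as in the residuals of these arrays and no effect, the preset correlation called a median of 6, 5 and 7 lists in the 3 comparisons, and the estimated correlation called 0 in every set. With this noise limma called 0 genes in every set without effect for the first 2 comparisons, and for GMP minus GMPP a mean of 8.08 and up to 404, with a median of 0. With changed genes present, false calls were then 3.93%, 2.67% and 7.04%.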

Results

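Transcript levels of Bifidobacterium longum subsp. infantis, a bacterium of the infant gut that grows on milk glycans, were measured on one-colour Agilent arrays with 4 probes for each of 2400 coding sequences. The 9 arrays came from 3 cultures each of 3 kinds: untreated bacteria in MRS broth, bacteria given bovine glycomacropeptide (GMP, the glycosylated peptide cut from milk kappa-casein) at 2 mg/ml, and bacteria given periodate-treated GMP (GMPP) at the same dose. Periodate is a reagent that oxidizes the sugars of glycoproteins. The median intensity per array lay between 697 and 1097, and 97.1% to 99.9% of probes were well above background. The number of arrays, 3 per group, limits the precision, and 3 against 3 cannot give an exact permutation p below 0.1. Genes carry the names and products of the array's design. Changes are log2 values of group means relative to the median gene, and list means are relative to the mean of all genes, both with the standard error (SE) and n = 3 arrays per group.

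Genes of low intensity differed most between the arrays, in all 3 groups. With the genes put in 10 classes of like size by mean intensity, the dimmest class had a median scaled intensity of 24.3, 29 and 60.4 on untreated replicates 1 to 3. It was 46.1, 58.6 and 77.9 on the GMP arrays and 107.1, 25 and 45 on the GMPP arrays. The brightest class, which holds many ribosomal protein genes, stayed between 12900 and 14700. Across genes, the loadings of the first principal component, with 70.6% of the variance, correlated with mean intensity at r = -0.69, and genes are not independent replicates. Untreated replicate 3 lay nearer to the GMP arrays, with correlations across genes of 0.995, 0.995 and 0.994, than to untreated replicates 1 and 2 (0.978 and 0.983). GMPP replicate 2 lay nearest to untreated replicates 1 and 2 (0.995 and 0.996), and GMPP replicate 1 correlated at 0.968 with both other GMPP arrays. GMPP replicate 3 was alone on slide 2 and in scan 2, with the other 8 arrays on slide 1. Untreated replicates 1 to 3 and GMP replicate 1 lay in row 1 of their slide, and all other arrays in row 2. Slide row and group therefore cannot be told apart for GMPP against untreated.

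**Figure D1:**
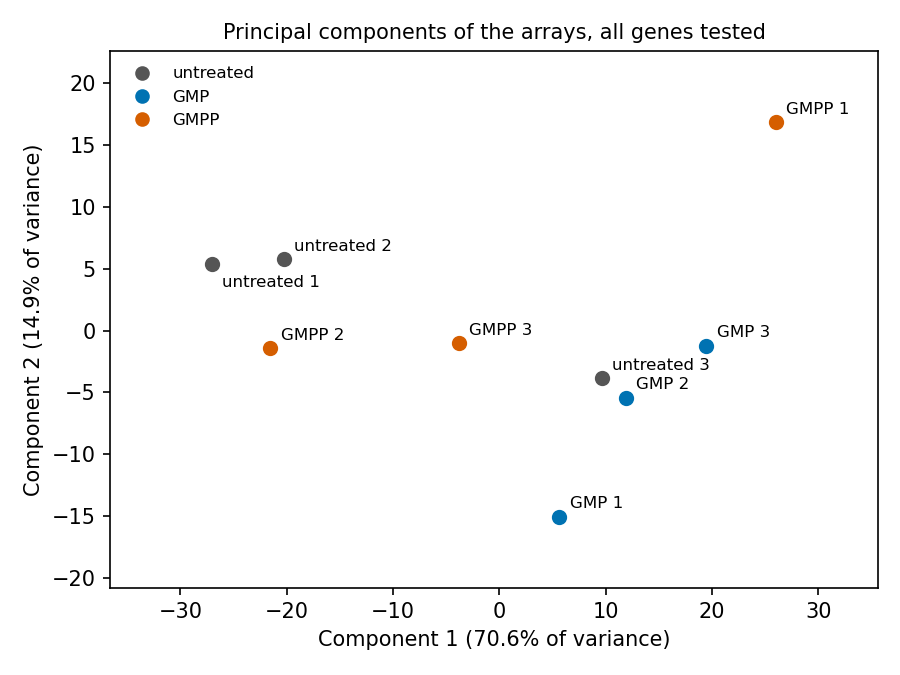
First and second principal components of the 9 arrays, in component score units, from the scaled log2 values of all genes tested; each point is an array, coloured by group. Untreated replicate 3 sits among the GMP arrays and GMPP replicate 2 beside untreated replicates 1 and 2.

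**Figure D2:**
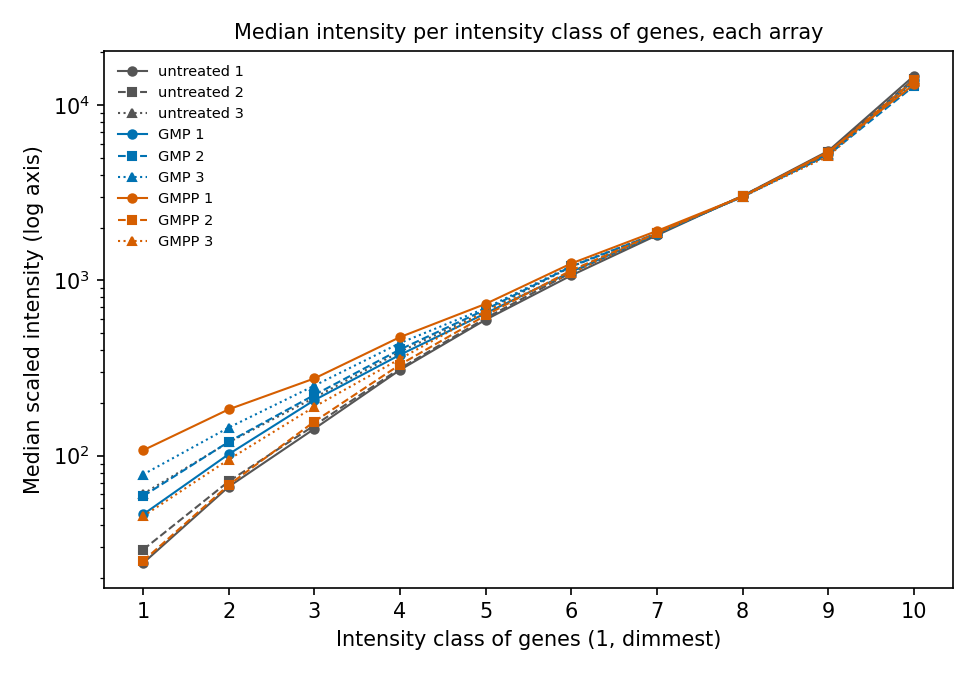
Median scaled intensity (log axis) of each of 10 intensity classes of genes, dimmest first, for each of the 9 arrays. The lines part in the dimmest classes, from 24.3 on untreated replicate 1 to 107.1 on GMPP replicate 1, and meet in the brighter ones.

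The first comparison, GMP against untreated, addresses how the bacterium's gene expression responds to the peptide. The 5 genes with the smallest p included 3 with consecutive locus tags. Blon_0638, a purine nucleosidase, which splits nucleosides into base and sugar, had a log2 change of -1.82 ± 0.25. Blon_0639, a transporter of the major facilitator superfamily, had -1.63 ± 0.26, and Blon_0640, a PfkB-domain protein of a family of sugar and nucleoside kinases, had -1.44 ± 0.23. For all 3 genes, the 3 GMP arrays lay below the 3 untreated arrays. Blon_0638 had a mean intensity of 893 with GMP against 2800 in untreated cultures. Its log2 value on untreated replicate 3, at 10.92, lay between the other untreated arrays (11.86 and 11.57) and the GMP arrays (9.48 to 10.00). Blon_1715, the formate acetyltransferase that splits pyruvate into formate and acetyl-CoA, had a change of -1.46 ± 0.25, and Blon_0491, an aminotransferase of low intensity, 0.63 ± 0.16. The value of Blon_0491 was 0.178 after quantile normalization, 0.235 with normexp background correction and 0.272 in the series matrix values. Each of these 5 genes had a limma adjusted p of 0.218.

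Genes for the use of milk glycans and central sugar metabolism were lower with GMP than other genes, by a limma camera test with a preset correlation. All 9 genes of hexosamine and lacto-N-biose use lay below the median gene, with a list mean of -1.02 ± 0.40 (adjusted p = 2.62e-05; adjusted p = 0.427 with an estimated correlation). Examples were Blon_2174, a conserved hypothetical protein by the array's annotation (-1.52 ± 0.37), the UDP-glucose 4-epimerase Blon_2171 (-0.86 ± 0.22) and nagB, which converts glucosamine-6-phosphate to fructose-6-phosphate (-0.99 ± 0.29). Of 13 genes of sialic acid use, 12 lay below the median gene, with a mean of -0.69 ± 0.24 (adjusted p = 0.00143; adjusted p = 0.587 with an estimated correlation). In it, 1 gene passed when adjusted over the list alone. Its examples were Blon_0640, the BNR-repeat glycosyl hydrolase Blon_0646 (-1.21 ± 0.43) and the exo-alpha-sialidase Blon_2348 (-0.45 ± 0.12). In the human milk oligosaccharide cluster H1, 21 of 26 genes lay below the median gene and the mean was -0.30 ± 0.07 (adjusted p = 0.00496; adjusted p = 0.292 with an estimated correlation). Examples in it were Blon_2349, a dihydrodipicolinate synthetase by annotation (-0.80 ± 0.14), the family 20 glycoside hydrolase Blon_2355 (-0.83 ± 0.17) and the solute-binding protein Blon_2351 (-0.87 ± 0.24). The bifid shunt, the fermentation route of bifidobacteria, with lower glycolysis had 17 of 21 genes below the median gene and a mean of -0.50 ± 0.17 (adjusted p = 2.14e-05; adjusted p = 0.292 with an estimated correlation). In it, 4 genes passed when adjusted over the list alone, against 0 over all genes. Its members included Blon_1715, the L-lactate dehydrogenase Blon_0840 (-0.71 ± 0.13) and the fructose-6-phosphate phosphoketolase Blon_1722 (-0.88 ± 0.20), the key enzyme of the shunt. Sugar transport genes, 25 of 32 below the median gene, had a mean of -0.31 ± 0.13 (adjusted p = 0.0137; adjusted p = 0.587 with an estimated correlation). They included the solute-binding proteins Blon_2380 (-0.99 ± 0.27) and, opposite, Blon_0321 (1.23 ± 0.37), and the glycoside hydrolase Blon_0268, listed for its sugar-binding domain (-0.90 ± 0.23). Glycoside hydrolases, 24 of 34 below the median gene, had a mean of -0.15 ± 0.08 (adjusted p = 0.0246; adjusted p = 0.675 with an estimated correlation). The beta-glucosidase Blon_1905 had a value of -0.89 ± 0.22. The calls of hexosamine use, sialic acid use, the bifid shunt and sugar transport each held in 25 of 26 alternatives, that of glycoside hydrolases in 24 and that of cluster H1 in 23. The estimated correlation ended each of these calls. Cluster H1 had a mean of -0.18 after quantile normalization and did not pass (adjusted p = 0.0576), and glycoside hydrolases had -0.10 without GMP replicate 1 (adjusted p = 0.0817). The fitted changes of the glycoside hydrolases had a mean of 0.07 and a median of -0.08, so that their signs differ. Of 12 genes fixed beforehand, glycan genes and the phosphoketolase, 11 lay below the median gene. They ranged from -1.52 for Blon_2174 to -0.17 ± 0.12 for the alpha-fucosidase Blon_2336, whose sign turned under quantile normalization. The other, the dim family 20 glycoside hydrolase Blon_0459, had a value of 1.29 ± 0.96.

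The lists of surface polysaccharide synthesis, cell wall and division, and purine and pyrimidine synthesis were also lower with GMP than other genes. Surface polysaccharide synthesis had 22 of 24 genes below the median gene and a mean of -0.41 ± 0.14 (adjusted p = 0.00269; adjusted p = 0.494 with an estimated correlation). Cell wall and division had 18 of 21 genes below it and a mean of -0.26 ± 0.12 (adjusted p = 0.0213; adjusted p = 0.587 with an estimated correlation). Both lists held Blon_0850, a peptidoglycan glycosyltransferase, which builds cell wall rather than surface polysaccharide (-0.99 ± 0.20). Other examples were the glycosyl transferases Blon_0629 (-0.84 ± 0.19) and Blon_0724 (-0.56 ± 0.15), the division protein FtsZ, Blon_0800 (-0.76 ± 0.19), and mraY of peptidoglycan synthesis (-0.71 ± 0.23). Purine and pyrimidine synthesis had 20 of 26 genes below the median gene and a mean of -0.26 ± 0.13 (adjusted p = 0.0246; adjusted p = 0.587 with an estimated correlation). Its inosine-5'-monophosphate dehydrogenase, Blon_0584, lay at -0.69 ± 0.15 but the dihydroorotate dehydrogenase Blon_2323 at 0.52 ± 0.16 and the phosphoribosylglycinamide synthetase Blon_0496 at 0.53 ± 0.20. Among random lists of the same intensity, cell wall and division lay at percentile 3.6 and purine and pyrimidine synthesis at 20.2, both inside the central 95%, and surface polysaccharide synthesis at 0.3, below it. Mobile elements and phage genes were higher than other genes, 51 of 68 above the median gene, with a mean of 0.30 ± 0.14 (adjusted p = 0.019; adjusted p = 0.791 with an estimated correlation). Examples were the phage integrases Blon_1739 (0.94 ± 0.32) and Blon_1149 (0.53 ± 0.21) and the transposase Blon_2098 (0.81 ± 0.29). Urease genes were higher too, 9 of 12 above the median gene, with a mean of 0.25 ± 0.14 (adjusted p = 0.0367; adjusted p = 0.675 with an estimated correlation). Among them were the accessory proteins UreF, Blon_0113 (0.38 ± 0.18), UreD, Blon_0115 (0.29 ± 0.17), and UreG, Blon_0114 (0.46 ± 0.31). Both of these lists hold dim genes, with median intensities of 411 and 388, and the median fitted change of all genes was 0.76 in the dimmest class, 0.28 in the fourth and -0.03 in the brightest. After quantile normalization neither list passed (adjusted p = 0.0694 and adjusted p = 0.0914). Cell wall and division, at -0.16 (adjusted p = 0.0694), and purine and pyrimidine synthesis, at -0.07 (adjusted p = 0.371), did not pass there either, and the latter had -0.12 in the series matrix values (adjusted p = 0.165). Of 26 alternatives, surface polysaccharide synthesis kept its call in 25, cell wall and division and mobile elements in 23 each, purine and pyrimidine synthesis in 21 and urease in 18.

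Across all 2396 genes, limma called 0 genes at an adjusted p of 0.05 for GMP against untreated, with 485 genes (308 higher, 177 lower) at an unadjusted p under 0.05 where chance gives 119.8. The groups did not overlap for 28.5% of genes, where chance gives 10%. These chance values are averages, and genes move together between arrays, so an excess need not come from the groups. The median fitted change was 0.17, with 65.5% of genes higher. It moved to -0.01 after quantile normalization (49.2% higher) and to 0.33 with spike-in scaling (78.9% higher). Camera called 11 of 25 lists, 9 lower and 2 higher, and 0 with an estimated correlation. The arrays of both groups separated fully in 6 of the 11. With spike-in scaling it called 7 lists, all of them lower. Urease and mobile elements, with means of 0.248 and 0.301 relative to all genes, did not pass there (camera adjusted p = 0.0698 and adjusted p = 0.0713). Spike-in scaling shifts all genes of an array alike, so such relative means cannot change under it. In simulated arrays with no effect and noise shared between genes as in these data, the preset correlation called a median of 6 lists and up to 17, and the estimated correlation called 0. Leaving out untreated replicate 3 gave 481 genes (339 higher, 142 lower), and leaving out both it and GMPP replicate 2 gave 685 (518 higher, 167 lower). Untreated replicate 3 lay nearest to the GMP arrays, so leaving it out widens the gap between the groups whatever its cause. These counts are therefore no support for an effect of GMP. Array quality weights gave 1849 genes and a trended robust prior 1.

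**Figure D3:**
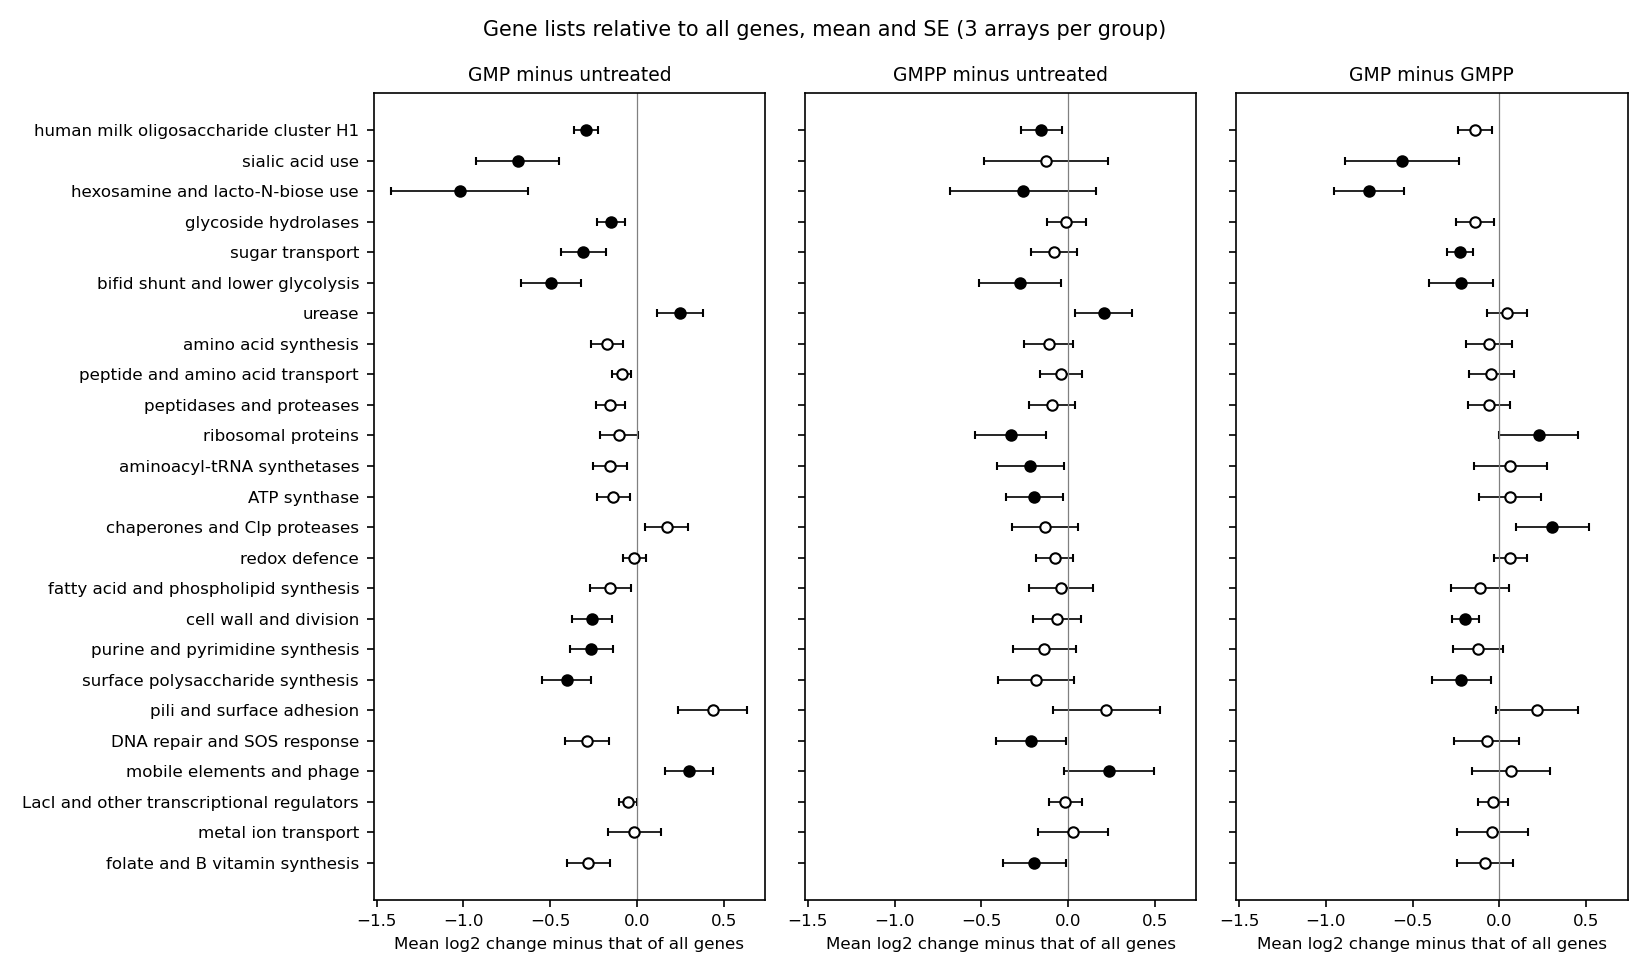
Mean log2 change of each of 25 gene lists minus that of all genes, with SE (n = 3 arrays per group), for the 3 comparisons; filled points passed the camera test with the preset correlation, and none passed with an estimated one. Hexosamine and lacto-N-biose use lies at -1.02 for GMP minus untreated and at -0.75 for GMP minus GMPP.

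The second comparison, GMPP against untreated, addresses the response to the peptide after periodate treatment. The lists of ribosomal proteins and of aminoacyl-tRNA synthetases were lower with GMPP than other genes. Of 56 ribosomal protein genes, 53 lay below the median gene, with a list mean of -0.33 ± 0.21 (n = 3; limma camera adjusted p = 1.33e-15; adjusted p = 0.301 with an estimated correlation). Examples were rplX (-0.56 ± 0.15), rplN (-0.55 ± 0.16) and rpsB (-0.49 ± 0.15), whose sign turned under quantile normalization and in the series matrix values. Aminoacyl-tRNA synthetases, which load tRNAs with amino acids, had 17 of 20 genes below the median gene and a mean of -0.22 ± 0.19 (adjusted p = 0.00093; adjusted p = 0.406 with an estimated correlation). The glycyl-tRNA synthetase Blon_0798 lay at -0.57 ± 0.23, thrS at -0.45 ± 0.20 and argS at -0.28 ± 0.10. Among random lists of the same intensity, the synthetases lay at percentile 2.9, inside the central 95%, and the ribosomal proteins at 0, below it. The fitted changes of the ribosomal proteins had a mean of -0.183, against -0.0961 for these random lists, a difference of -0.087. Their mean of -0.33 relative to all genes therefore also holds the trend with intensity. After quantile normalization neither list passed (adjusted p = 0.175 for each), with means of -0.07 and -0.08. Without GMPP replicate 1 the synthetases had a mean of -0.08 and did not pass (adjusted p = 0.147). Of 26 alternatives, the ribosomal proteins kept their call in 24, with means from -0.525 to -0.071, and the synthetases in 20, with means from -0.437 to -0.076.

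The bifid shunt, cluster H1 and hexosamine lists were lower with GMPP than other genes as well. Sugar transport, with a mean of -0.08 ± 0.13 (adjusted p = 0.454), and glycoside hydrolases, with -0.01 ± 0.11 (adjusted p = 0.349), did not pass. The bifid shunt and lower glycolysis had 18 of 21 genes below the median gene and a mean of -0.28 ± 0.24 (adjusted p = 1.47e-06; adjusted p = 0.189 with an estimated correlation). In this list, gpmA lay at -0.41 ± 0.12, the glyceraldehyde-3-phosphate dehydrogenase Blon_0900 at -0.61 ± 0.23 and Blon_1715 at -0.62 ± 0.25. The human milk oligosaccharide cluster H1 had 22 of 26 genes below the median gene and a mean of -0.16 ± 0.12 (adjusted p = 0.00093; adjusted p = 0.189 with an estimated correlation). The RbsD or FucU protein Blon_2337 lay at -0.49 ± 0.14, Blon_2349 at -0.40 ± 0.14 and the sugar transporter Blon_2332 at -0.32 ± 0.11. Its mean was -0.06 without GMPP replicate 1 (adjusted p = 0.147) and -0.06 after quantile normalization (adjusted p = 0.228), and it passed in neither. This list lay at percentile 4 of random lists of the same intensity, inside their central 95%. Hexosamine and lacto-N-biose use, 8 of 9 genes below the median gene, had a mean of -0.26 ± 0.42 (adjusted p = 0.039; adjusted p = 0.75 with an estimated correlation). That call held in 15 of 26 alternatives, with means from -0.81 to -0.03, against 25 for the bifid shunt and 22 for cluster H1. The mean of the bifid shunt ranged from -0.583 to -0.126 over the alternatives. In the hexosamine list, Blon_2171 lay at -0.47 ± 0.22, Blon_2174 at -0.63 ± 0.37 and nagB at -0.32 ± 0.29. Sialic acid use had a mean of -0.13 ± 0.36 (adjusted p = 0.347). Of the 12 fixed genes, 11 lay below the median gene, from -0.63 for Blon_2174 to -0.15 ± 0.17 for Blon_2355. Among them, Blon_2335, at -0.26 ± 0.14, turned sign under quantile normalization, and the other gene, Blon_0459, had a value of 0.79 ± 0.96.

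ATP synthase, DNA repair and folate synthesis lists were also lower with GMPP than other genes, and mobile element and urease lists higher. Among random lists of the same intensity, the first 3 lay at percentiles 39.4, 2.8 and 7.4, all inside the central 95%. ATP synthase genes, 9 of 13 below the median gene, had a mean of -0.20 ± 0.17 (adjusted p = 0.00143; adjusted p = 0.215 with an estimated correlation) that turned to 0.02 under quantile normalization. Its members included the ATP synthase subunits Blon_0307 (-0.50 ± 0.15, turning sign under quantile normalization) and Blon_0305 (-0.41 ± 0.12), and 5 ATPase subunits of other complexes, such as the phosphonate transporter's Blon_0022 (0.41 ± 0.20). DNA repair had 19 of 23 genes below the median gene and a mean of -0.21 ± 0.20 (adjusted p = 0.0201; adjusted p = 0.189 with an estimated correlation). Blon_1714, the activating enzyme of pyruvate formate-lyase (-0.96 ± 0.31), and pyruvate kinase, Blon_1745 (-0.53 ± 0.24), are fermentation and glycolysis enzymes in that list. By contrast, recO of DNA repair had a value of 0.23 ± 0.13, and without 5 such enzymes the list did not pass (adjusted p = 0.46). Folate and B vitamin synthesis, 18 of 21 genes below the median gene, had a mean of -0.20 ± 0.18 (adjusted p = 0.0276; adjusted p = 0.189 with an estimated correlation). The folate and DNA repair calls each held in 15 of 26 alternatives, with means from -0.42 to -0.06 and from -0.47 to -0.07, and those of ATP synthase in 21, mobile elements in 21 and urease in 17. Without GMPP replicate 1 none of these 5 lists passed, with means of -0.06 for ATP synthase (adjusted p = 0.172), -0.07 for DNA repair (adjusted p = 0.446), -0.06 for folate synthesis (adjusted p = 0.241), 0.06 for mobile elements (adjusted p = 0.27) and 0.12 for urease (adjusted p = 0.161). After quantile normalization only mobile elements passed. The thiamine-phosphate diphosphorylase Blon_0796 lay at -0.46 ± 0.17, the dihydropteroate synthase Blon_0551 at -0.49 ± 0.19 and the riboflavin kinase Blon_2195 at 0.05 ± 0.12. Mobile elements and phage genes, 56 of 68 above the median gene, had a mean of 0.23 ± 0.26 (adjusted p = 0.00093; adjusted p = 0.75 with an estimated correlation). The integrase Blon_1149 lay at 0.34 ± 0.21, the prophage repressor Blon_1764 at 0.28 ± 0.19 and the phage structural protein Blon_1815 at 1.03 ± 0.68. Urease genes, 11 of 12 above the median gene, had a mean of 0.20 ± 0.17 (adjusted p = 0.0193; adjusted p = 0.75 with an estimated correlation). Their ureC lay at 0.17 ± 0.14, Blon_0113 at 0.22 ± 0.18 and the nickel transporter Blon_0109 at 0.19 ± 0.18. The median fitted change of all genes was 0.50 in the dimmest class, 0.20 in the fourth, where the mobile elements' median intensity of 411 lies, and -0.10 in the brightest, where the ribosomal proteins' median of 19400 lies.

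No single gene passed for GMPP against untreated: limma called 0 genes, with 57 (36 higher, 21 lower) at an unadjusted p under 0.05. The groups did not overlap for 4.8% of genes, where chance gives 10%. The 5 genes with the smallest p were the hypothetical protein Blon_1797 (-0.81 ± 0.21), the ABC transporter protein Blon_2009 (-0.51 ± 0.12), the RpiR-family regulator Blon_0024 (0.53 ± 0.20), the phosphonate transporter subunit Blon_0021 (0.50 ± 0.20) and rplX, each with a limma adjusted p of 0.885. The median fitted change was 0.10, with 70.5% of genes higher. It moved to 0.00 after quantile normalization (50.4% higher) and to 0.28 with spike-in scaling (90.7% higher). Camera called 10 of 25 lists, 8 lower and 2 higher, and 0 with an estimated correlation, and in all 10 the arrays of both groups overlapped. The count was 2 after quantile normalization (1 higher), 6 with spike-in scaling (0 higher), 3 in the series matrix values (1 higher), and 4 with slide as a block. It was 6, 3 and 4 without untreated replicate 1, GMPP replicate 1 and GMPP replicate 3, the last leaving slide 1 alone. Simulated arrays with no effect gave a median of 5 lists and up to 15. Leaving out both untreated replicate 3 and GMPP replicate 2 gave 175 genes (170 higher, 5 lower). GMPP replicate 2 lay nearest to untreated replicates 1 and 2, so this widens the gap whatever its cause and is no support for an effect. The arrays left also differ in the level of dim genes. Their dimmest class had medians of 24.3 and 29 on untreated replicates 1 and 2, and 107.1 and 45 on GMPP replicates 1 and 3.

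The third comparison, GMP against GMPP, addresses what periodate treatment of the peptide changed in the response, and tests the difference of the other effects directly. The 3 genes with the smallest p were also among the first 5 for GMP against untreated, but both comparisons share the 3 GMP arrays, which makes such overlap more likely without any effect. Blon_0638 had a log2 change of -1.95 ± 0.25 (n = 3; limma adjusted p = 0.129), Blon_0640 of -1.58 ± 0.23 (adjusted p = 0.168) and Blon_0639 of -1.59 ± 0.26 (adjusted p = 0.275). For each, the 3 GMP arrays lay below the 6 other arrays. The mean intensity of Blon_0638 was 893 with GMP and 3320 with GMPP. The ribosomal protein L32 gene rpmF copy 2 (-0.95 ± 0.20) and Blon_2085, of unknown function (-0.83 ± 0.17), followed, each with a limma adjusted p of 0.429.

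**Figure D4:**
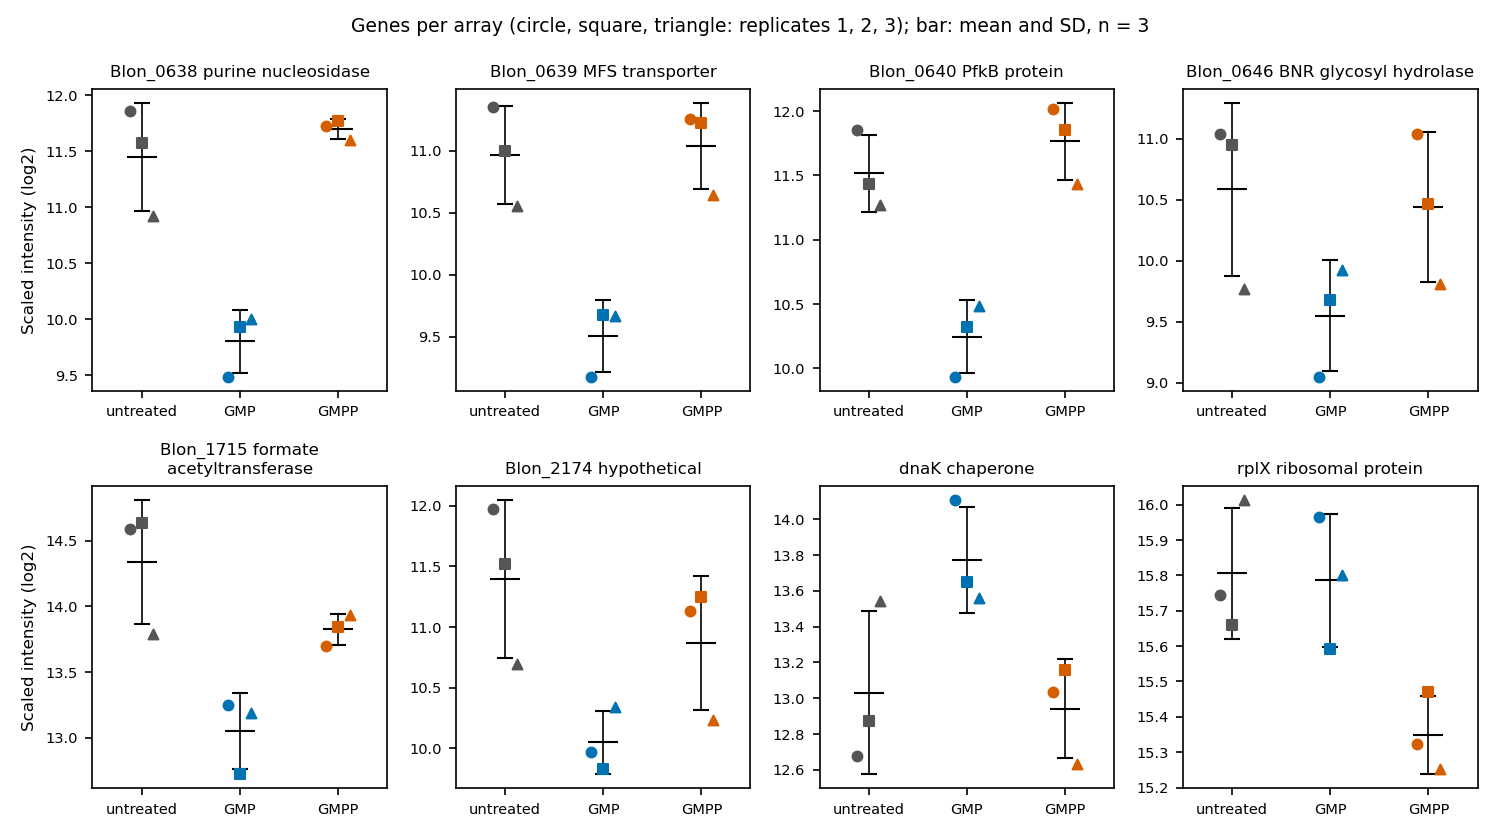
Scaled log2 intensity of 8 genes on each of the 9 arrays, by group, with mean and SD (n = 3). For Blon_0638, Blon_0639 and Blon_0640 the 3 GMP arrays lie below all 6 others.

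The lists of hexosamine use, sialic acid use, sugar transport and the bifid shunt were lower with GMP than with GMPP, relative to other genes. Hexosamine and lacto-N-biose use had 9 of 9 genes below the median gene and a mean of -0.75 ± 0.20 (adjusted p = 0.000498; adjusted p = 0.66 with an estimated correlation). Its examples were the transporter membrane proteins Blon_2176 (-1.28 ± 0.43) and Blon_2175 (-0.99 ± 0.38) and Blon_2174 (-0.88 ± 0.37). Sialic acid use had 11 of 13 genes below the median gene and a mean of -0.56 ± 0.33 (adjusted p = 0.00529; adjusted p = 0.66 with an estimated correlation). In this list Blon_0646 lay at -0.95 ± 0.43 and the LacI regulator Blon_0641 at -0.60 ± 0.21, and 1 gene passed when adjusted over the list alone. Sugar transport had 24 of 32 genes below the median gene and a mean of -0.23 ± 0.07 (adjusted p = 0.025; adjusted p = 0.66 with an estimated correlation). Examples were the solute-binding proteins Blon_0883 (-0.71 ± 0.21) and Blon_2351 (-0.73 ± 0.24) and the sugar transporter Blon_0431 (-0.45 ± 0.13). The bifid shunt and lower glycolysis had 15 of 21 genes below the median gene and a mean of -0.22 ± 0.18 (adjusted p = 0.028; adjusted p = 0.66 with an estimated correlation). Here Blon_1715 lay at -0.83 ± 0.25, Blon_0840 at -0.36 ± 0.13 and the phosphoglycerate mutase Blon_1642 at -0.55 ± 0.22. Relative to all genes, the GMP and GMPP arrays overlapped for sialic acid use and the bifid shunt. Of 26 alternatives, the calls held in 25 for hexosamine use, 22 for sialic acid use, 20 for sugar transport and 17 for the bifid shunt. Single arrays moved some of these means: without GMPP replicate 1, sialic acid use had -0.33 (adjusted p = 0.216), and without GMPP replicate 2, the bifid shunt had -0.07 (adjusted p = 0.61) and sugar transport -0.17 (adjusted p = 0.0612). The human milk oligosaccharide cluster H1, with a mean of -0.14 ± 0.10 (adjusted p = 0.3), and glycoside hydrolases, with -0.14 ± 0.11 (adjusted p = 0.0599), did not pass. Of the 12 fixed genes, 8 lay below the median gene, including Blon_2355 (-0.67 ± 0.17) and the phosphoketolase Blon_1722 (-0.39 ± 0.20), and 4 above, including the beta-galactosidase Blon_2016 (0.23 ± 0.23). The hexosaminidase-family gene Blon_0732, at 0.00 ± 0.17, turned sign with normexp background correction.

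The lists of ribosomal proteins and of chaperones were higher with GMP than with GMPP, relative to other genes, and those of cell wall and surface polysaccharide synthesis lower. Without GMPP replicate 1 neither of the higher lists passed, with a mean of 0.08 (adjusted p = 0.0523) for ribosomal proteins and 0.21 (adjusted p = 0.112) for chaperones. Without GMPP replicate 2 neither of the lower lists passed, with a mean of -0.10 for surface polysaccharide synthesis and -0.12 for cell wall and division (adjusted p = 0.314 for each). Of 26 alternatives, the calls of ribosomal proteins and chaperones held in 24 each, that of surface polysaccharide synthesis in 22 and that of cell wall and division in 18. Aminoacyl-tRNA synthetases, with a mean of 0.06 ± 0.21 (adjusted p = 0.204), did not pass. Ribosomal proteins had 50 of 56 genes above the median gene and a mean of 0.23 ± 0.23 (adjusted p = 1.57e-06; adjusted p = 0.66 with an estimated correlation). The L19 gene rplS lay at 0.77 ± 0.26 and, opposite, the L36 gene Blon_1969 at -0.78 ± 0.18 and rpmF copy 2 at -0.95 ± 0.20. Chaperones and Clp proteases, which fold or degrade proteins, had 8 of 10 genes above the median gene and a mean of 0.31 ± 0.21 (adjusted p = 0.0129; adjusted p = 0.66 with an estimated correlation). Among them dnaK lay at 0.77 ± 0.26, the GrpE gene Blon_0142 at 0.71 ± 0.29 and groES at 0.39 ± 0.16. The log2 value of dnaK on untreated replicate 3, at 13.55, lay with the GMP arrays (13.56 to 14.11) rather than with untreated replicates 1 and 2 (12.68 and 12.87). Cell wall and division had 18 of 21 genes below the median gene and a mean of -0.20 ± 0.08 (adjusted p = 0.025; adjusted p = 0.66 with an estimated correlation). Its Blon_0850 lay at -0.73 ± 0.20, mraY at -0.65 ± 0.23 and Blon_0800 at -0.46 ± 0.19. Surface polysaccharide synthesis had 20 of 24 genes below the median gene and a mean of -0.22 ± 0.17 (adjusted p = 0.0129; adjusted p = 0.66 with an estimated correlation). The group 1 glycosyl transferase Blon_0629 lay at -0.75 ± 0.19 and the family 4 glycosyl transferase Blon_0583 at -0.43 ± 0.12.

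Over all genes, limma called 0 between GMP and GMPP, with 267 (122 higher, 145 lower) at an unadjusted p under 0.05. The groups did not overlap for 26.2% of genes, where chance gives 10%. Genes move together between arrays, so an excess need not come from the groups. The split of GMP replicate 1 with GMPP replicates 2 and 3 against the other arrays gave 495 genes at that unadjusted p, and every further split fewer than 267. The count at an adjusted p of 0.05 was 2 after quantile normalization, 3 with a trended robust prior, and 1 each with normexp, the series matrix values, array quality weights and without untreated replicate 3, all of them lower with GMP. Blon_0638 was called in each of these 6 settings. The median fitted change was 0.06. Camera called 8 of 25 lists, 6 lower and 2 higher, and 0 with an estimated correlation. The arrays of both groups separated fully in 3 of the 8. Simulated arrays with no effect gave a median of 7 lists and up to 13. The count was 5 after quantile normalization (2 higher), 5 with array quality weights, 3 without GMPP replicate 1 (0 higher) and 4 without both untreated replicate 3 and GMPP replicate 2 (3 higher).

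Across genes, the changes with GMP and with GMPP, each against untreated cultures, correlated at r = 0.699 (Spearman 0.69), with a covariance of 0.101. Both changes share the 3 untreated arrays, and simulated groups with no effect gave a mean r of 0.421 (central 95% from -0.753 to 0.973). Their mean covariance was 0.0533, which leaves a difference of 0.0475, and their central 95%, from -0.0529 to 0.257, holds the observed covariance. Too few untreated arrays exist to split them, so some or all of this difference may come from these shared arrays. The correlation was 0.214 without GMPP replicate 1, 0.401 without untreated replicate 1 and 0.457 after quantile normalization. Genes are not independent replicates, and dim genes such as those of mobile elements were higher in both comparisons.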

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

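The tests of array background, of a floor in the labelled sample, of exchanged labels, of single probes and of both doubted arrays were chosen after the results were seen. The check against random lists of the same intensity was made after the trend with intensity was seen.

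A direct test of the difference between the effects of GMP and GMPP called 8 gene lists (limma camera with a preset correlation, adjusted p below 0.05 for each, and adjusted p = 0.66 for each with an estimated correlation). Simulated arrays with no effect and noise shared between genes gave a median of 7 lists and up to 13 by this test. The count of 8 therefore does not tell an effect from such noise. The means relative to all genes were -0.753 for hexosamine and lacto-N-biose use, -0.562 for sialic acid use, -0.226 for sugar transport, -0.22 for the bifid shunt and lower glycolysis, -0.197 for cell wall and division, -0.22 for surface polysaccharide synthesis, 0.227 for ribosomal proteins and 0.306 for chaperones and Clp proteases. Of these, sialic acid use, sugar transport, cell wall and division, ribosomal proteins and chaperones did not pass without GMPP replicate 1, and sugar transport, the bifid shunt, cell wall and division and surface polysaccharide synthesis did not pass without GMPP replicate 2, where the bifid shunt had -0.075 and surface polysaccharide synthesis -0.096.

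The 6 arrays of a comparison can be split in only 10 ways, too few for a share under 0.05. For GMP minus untreated, the real split gave 0 genes and 11 lists, and the highest of the other splits gave 0 genes and 10 lists. For GMPP minus untreated, the real split gave 0 genes and 10 lists, and the highest others gave 564 genes and 13 lists. The split with 564 genes set untreated replicates 1 and 2 with GMPP replicate 2 against the other 3 arrays, which points to a structure of the samples other than the labelled groups. For GMP minus GMPP, the real split gave 0 genes and 8 lists, and the highest others gave 0 genes and 11 lists.

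Blon_0638, Blon_0639 and Blon_0640 were lower on all 3 GMP arrays than on all 6 others, although none of them passed the limma test over all genes in the chosen setting; of the alternatives that kept all 9 arrays, Blon_0638 passed for GMP minus GMPP in 5, Blon_0640 in 2 and Blon_0639 in 1, and for GMP minus untreated Blon_0638 in 2 and the others in 1 each. A faulty or cross-hybridizing probe is argued against, since each of the 12 probes showed at least 95.1% of its gene's change. A trend with intensity is argued against, since the 200 genes nearest in intensity to each had median changes no farther from 0 than 0.102. For GMP minus GMPP, the doubted array GMPP replicate 2 is argued against as the source. Without it and untreated replicate 3, each gene kept at least 94% of its change. For GMP minus untreated the same check decides nothing. Untreated replicate 3 lay towards the GMP arrays, for Blon_0638 below both other untreated arrays, so leaving it out enlarges the change. Chance stays open, as does any other difference shared by the 3 GMP cultures or their arrays, which was not tested. A response of these consecutive genes to GMP that periodate treatment removes stays open too. It is only a hypothesis, found and tested on the same arrays.

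Untreated replicate 3 lay nearest to the GMP arrays. An exchange of labels with GMPP replicate 2 stays open. The highest correlation of untreated replicate 3 with GMPP replicate 1 or 3 was 0.983, below its lowest with a GMP array, 0.994. However, GMPP replicates 1 and 3 themselves correlated at only 0.968, so these correlations do not tell GMPP cultures from others. The split that makes this exchange called 564 genes. It regroups the arrays whose likeness raised the doubt, and also parts them by the level of dim genes, so it adds no support. A trend with intensity as the whole source is argued against, since after quantile normalization its lowest correlation with a GMP array was 0.995, above its highest with untreated replicates 1 and 2, 0.984. That it is a GMP culture under a wrong label could not be tested well: on the 50 genes that best part GMP from GMPP it lay at 0.69 between the GMPP mean (0) and the GMP mean (1), below the lowest GMP array left out of the choice of genes (0.77), but GMPP replicate 1, left out likewise, lay at 0.95, so the scale does not part the groups and the bound set beforehand was wrong. The design names no difference between the untreated cultures, so no biological explanation was tested.

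Dim genes, mobile elements and urease genes among them, were brighter on some arrays than on others of the same group. A background left in the processed signal is argued against, since the median negative control signal spanned only 2.85 intensity units over the 9 arrays. The median of the dimmest of 10 intensity classes of genes spanned 96.9 before scaling. The processed signal is already background-subtracted, so flat controls cannot tell whether the subtraction itself differed between arrays for the gene probes. A floor added to every gene in the labelled sample, such as carried-over DNA, stays open: the excess of GMPP replicate 1 over untreated replicate 1 differed by 2.01-fold between the 4 dimmest classes while the level differed by 12.7-fold, which is neither constant nor proportional. Against 10000 random lists of the same intensity, mobile elements lay at percentile 100 for GMP and 100 for GMPP and urease genes at 98.6 for GMPP, above what the trend with intensity alone gives, while urease genes lay at 88.3 for GMP, within it, as did 3 of the 11 called lists for GMP and 5 of the 10 for GMPP in all, against 0 of the 8 for GMP minus GMPP. These random lists leave out the correlation between genes, and quantile normalization, which takes the trend away, ended the calls of both lists for GMP (list means of 0.165 and 0.16 relative to all genes) and of urease for GMPP but kept that of mobile elements for GMPP (0.169); without GMPP replicate 1 that last mean was 0.06 and did not pass, so a response of these genes to the supplements was not told from the state of single arrays.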

How the results depend on the processing

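Leaving out untreated replicate 3 and GMPP replicate 2 together, and the lists without stray members, were chosen after the results were seen. Both arrays lay nearest to arrays of another group. Leaving them out therefore widens the gaps between untreated and treated groups whatever their cause, and higher counts without them are no support for an effect. Genes called for GMP minus untreated went from 0 to 1 with a trended robust prior, 1849 with array quality weights (1284 higher, 565 lower) and 685 without both doubted arrays, and ranged from 0 to 481 when each array was left out, 481 without untreated replicate 3. The weights stopped before convergence and gave untreated replicate 2 a weight of 17.4 against 0.182 for untreated replicate 3. Genes called for GMPP minus untreated went from 0 to 175 without both doubted arrays and were 0 without any single array. Genes called for GMP minus GMPP went from 0 to 2 with quantile normalization, 1 with normexp, 1 in the series matrix values, 3 with a trended robust prior and 1 with array weights, and ranged from 0 to 1 over left-out arrays. Lists for GMP minus untreated went from 11 to 7 with spike-in scaling and 0 with an estimated correlation, and ranged from 10 to 12 over left-out arrays. Lists for GMPP minus untreated went from 10 to 2 with quantile normalization, 6 with spike-in scaling, 3 in the series matrix values, 4 with the slide as a block and 0 with an estimated correlation, and ranged from 3 without GMPP replicate 1 to 14 without untreated replicate 3. Lists for GMP minus GMPP went from 8 to 5 with quantile normalization, 5 with array weights, 4 without both doubted arrays and 0 with an estimated correlation, and ranged from 3 without GMPP replicate 1 to 10 without GMPP replicate 3. The correlation of both effects went from 0.699 to 0.457 with quantile normalization and 0.486 in the series matrix values, and ranged from 0.214 without GMPP replicate 1 to 0.89 without untreated replicate 3. The ATP synthase list for GMPP minus untreated reversed to 0.019 with quantile normalization. The slide block leaves GMPP replicate 3 without weight, as it is alone on its slide; for the other changes the cause was not tested. Called lists kept their direction and call in 257 of 286, 195 of 260 and 172 of 208 values over the alternatives of the 3 comparisons. With the replicate number as a block the counts were 0, 0 and 0 genes and 12, 10 and 8 lists. The correlation stayed at 0.699, which this block cannot change. Arrays of one number deviated together at r from -0.694 to 0.63, so the numbers do not pair the cultures of all 3 groups. Between untreated and GMP arrays, r was 0.217, 0.18 and 0.309 for replicates 1 to 3, so a weak pairing of those cultures stays open. With 97.1% or more of probes above background on each array, signal over background limits only the dimmest genes.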

Other observations

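No test in this part was chosen after its result was seen.

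Chaperones and surface genes lay above other genes with GMP without passing the test. Chaperones and Clp proteases had a mean of 0.17 ± 0.12 relative to all genes for GMP minus untreated, with 8 of 10 genes above the median gene (limma camera adjusted p = 0.0634; n = 3). Pili and surface adhesion genes, such as sortases and anchored surface proteins, had a mean of 0.44 ± 0.20 with 9 of 10 genes above the median gene (adjusted p = 0.0648), and 0.22 ± 0.31 for GMPP minus untreated (adjusted p = 0.347). Their median intensity of 214 puts them among the dim genes, which were brighter on untreated replicate 3, the GMP arrays and GMPP replicates 1 and 3 than on the other 3 arrays.

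Genes for the supply of amino acids did not pass the test in any of the 3 comparisons. Amino acid synthesis had means of -0.17 ± 0.09 for GMP (limma camera adjusted p = 0.273) and -0.11 ± 0.14 for GMPP (adjusted p = 0.213), each against untreated cultures. Peptide and amino acid transport had -0.09 ± 0.06 (adjusted p = 0.74) and -0.04 ± 0.12 (adjusted p = 0.999), and peptidases and proteases -0.15 ± 0.09 (adjusted p = 0.697) and -0.09 ± 0.13 (adjusted p = 0.347). Redox defence had -0.02 ± 0.07 (adjusted p = 0.273) and -0.08 ± 0.11 (adjusted p = 0.989), where the test's direction was upward in both, opposite to the mean. Fatty acid and phospholipid synthesis had -0.15 ± 0.12 (adjusted p = 0.962) and -0.04 ± 0.19 (adjusted p = 0.496), transcriptional regulators -0.05 ± 0.05 (adjusted p = 0.729) and -0.02 ± 0.10 (adjusted p = 0.347), and metal ion transport -0.01 ± 0.15 (adjusted p = 0.954) and 0.03 ± 0.20 (adjusted p = 0.738). For GMP minus GMPP none of these 7 lists passed, with means from -0.11 ± 0.17 for fatty acid and phospholipid synthesis to 0.06 ± 0.09 for redox defence.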
